A study of Mus musculus with 2 samples.

How the data were processed

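H3K9me3 was measured by chromatin immunoprecipitation followed by sequencing in stomach tissue of embryonic day 16.5 mice, in 2 samples labelled as biological replicates 1 and 2 of 1 group. Per the labels, both libraries held fragments of 300 to 500 bp and both pools held male and female embryos. Replicate 2 pooled 41 embryos, and the number in replicate 1 is not given in the sources used here. The sample of each list came from the labels and from the deposited descriptions of the files, never from values.

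The authors deposited 4 peak lists on the mm10 assembly, 1 for each replicate, 1 for both replicates pooled and 1 of replicated peaks. Per the file headers and deposited descriptions, the list of replicate 2 derives from its filtered alignments and 1 further file, the list of replicate 1 from its alignments and 2 further files, and the pooled list from both alignments and 2 further files. The kind of those further files is not described there, and the labels name a possible control experiment. The replicated list derives from the 3 other lists by a rule not given in the sources used here. The aligner, the peak caller, its version, its threshold and the treatment of reads with several matches are likewise not given in the sources used here.

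Each peak carries a deposited signal value in column 7, read here as a ratio (fold enrichment) from the format and the range of values. Columns 8 and 9 hold deposited −log10 p and −log10 q values. The lists were used as deposited. The smallest −log10 p was close to 2 in every list, and peaks with q above 0.05 made up 57.1% of replicate 1, 69.6% of replicate 2, 24.1% of the pooled list and 5.28% of the replicated list. Calls are therefore permissive, and a threshold of −log10 q of 5 was one of the alternatives. Read depth is unknown, so no counting interval is given. All 13825 replicated peaks had the same coordinates as a pooled peak.

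Coordinates are those of mm10, which is GRCm38. Genes came from GENCODE release M21, and sequence and repeat marking (lower case) from GRCm38.p6, both of that build. Analyses of genes covered the 19 autosomes, X and Y. The annotation had 21938 protein-coding genes there, of which 21911 with distinct symbols entered the list tests. Positions are counted from 1.

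Gene lists, tests and alternatives were fixed before the data were examined. For each of 23 lists, the share of protein-coding genes with a replicated peak over the body was compared with that of all other protein-coding genes. All peaks of a chromosome were moved by 1 random distance, wrapping round within the span that holds sequence, 10000 times. The tested quantity, which also gives the direction, is the difference between the 2 shares relative to its mean over shifts, while the shifted share printed beside a list is the mean of the list's own share. The permutation test is two-sided, its smallest p is 0.0001, and p was adjusted by Benjamini-Hochberg over the 23 lists. These p-values concern the placement of peaks along the genome, not the spread between animals. The lists were zinc finger genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, Rhox genes, keratin-associated proteins, defensins, bitter taste receptors, core histones, ribosomal proteins, imprinted genes, germline genes, 2-cell stage genes, housekeeping genes, genes of H3K9 methylation and heterochromatin, and marker genes of stomach epithelium, stomach mesenchyme and muscle, enteric neurons and glia, endothelium and blood, liver and pancreas, intestine and brain. Families were matched by symbol, and the zinc finger list takes any symbol of that kind, whether or not the protein has a KRAB domain.

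Replicate overlap, genomic features and repeat content were tested in the same way with 1000 shifts. A promoter was the 1 kb either side of the transcription start site of a protein-coding gene, and a peak was placed by its midpoint. In zinc finger genes, a peak over the last exon of the longest transcript was set against one near the start site by an exact McNemar test. Signal values of overlapping peaks were compared by Spearman rho without a p, with a bootstrap of 500 draws over chromosomes.

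The text names the 10 protein-coding genes with the most sequence under replicated peaks, the 10 of 2 kb or longer with the largest share covered, the 10 replicated peaks with the highest signal value and the 5 widest. Of each list it names all marked members where these are 6 or fewer, and otherwise the 4 with the most sequence covered. The non-coding imprinted genes were described as fixed beforehand. The 9 germline genes marked at the start site, and Cyp3a11, were named after their values were seen. Several peaks tied at the lowest signal value named. The tie was broken by −log10 p, then by width, a rule set after the values were seen, and it decided which tied peaks are named.

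Alternatives were the pooled list, the list of either replicate alone, peaks with −log10 q of 5 or more, at least 500 bp of the body covered, peaks within 1 kb of the start site, Fisher's exact test, 10000 random lists matched on deciles of gene length, a promoter of 2.5 kb, and other rules of overlap. Added after the data were seen were the first exon alone, pooled peaks with 50% overlap in both replicates, and peaks with −log10 q of 5 or more by chromosome.

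The tests were tested on simulated data made by moving the replicated peaks at random. Of 480 list tests over 21911 genes with no effect, 4.17% fell under 0.05. Peaks without effect were moved by the same rule that the tests use. Such rates therefore check the calculation, not whether shifts suit real peaks. With peaks added in 10%, 20% or 40% of the genes of a random list of 200, and likewise of the zinc finger list, all 5 simulations of each size were called. For replicate overlap, 1 of 20 simulations without effect and 20 of 20 with 5% of peaks placed on the other list fell under 0.05. For exons, 2 of 20 without effect and 20 of 20 with 3% of peaks placed on exons did so, and for repeats 0 of 20 without effect.

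Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and minimap2 2.31 to find copies of peak sequences. Signal tracks and alignments were not analysed here.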

Results

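Trimethylation of histone H3 at lysine 9 (H3K9me3), a mark of heterochromatin and silenced genes, was profiled by chromatin immunoprecipitation followed by sequencing in mouse stomach at embryonic day 16.5. The 2 samples were biological replicates of 1 group, each a pool of male and female B6NCrl embryos, and replicate 2 came from 41 embryos. The peak list of replicate 1 held 29504 peaks covering 7.68 Mb and that of replicate 2 held 44132 peaks covering 12.04 Mb. A pooled list of both replicates held 37115 peaks, and a replicated list kept 13825 of them, covering 5.67 Mb of the mm10 genome with a median width of 337 bp. Read depth is unknown, since the peak lists give no read counts. With 1 group, no condition was compared. The series describes where the mark lies and how far the replicates agree, and gives no stated aim beyond the profile itself.

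Most replicated peaks lay outside protein-coding genes. Of 13626 replicated peaks on the 21 chromosomes, 58.7% had their midpoint between protein-coding genes, 33.9% in an intron, 5.88% in an exon and 1.49% within 1 kb of a transcription start site. Exons held 1.67 times the share that peaks shifted along the same chromosome gave (3.53%), and introns held less than shifted peaks (36.8%). By circular-shift permutation test, two-sided, p was 0.000999 for exons and 0.004 for introns, where 0.000999 is the smallest value that 1000 shifts can give. The shares for promoters (p = 0.193) and for sequence between genes (p = 0.498) did not pass 0.05 in the same permutation test. Both depend on the list used, since the share between genes was higher than for shifted peaks in the pooled list (61.5%) and in each replicate (60.9% and 62.3%, permutation p = 0.000999 each), and the promoter share was lower in the pooled list (1.32%, permutation p = 0.002) and in that of replicate 1 (1.41%, permutation p = 0.005). The 2343 replicated peaks with −log10 q of 5 or more differed, with 11.0% in exons, 2.69% at promoters against 1.67% for shifted peaks (permutation p = 0.004), and 49.98% between genes, lower than for shifted peaks (permutation p = 0.000999). In that subset the intron share, 36.3%, no longer differed from shifted peaks (permutation p = 0.804), and the same held for pooled peaks found in both replicates, at 35.2% (permutation p = 0.136).

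A replicated peak lay over the body of 2905 of 21911 protein-coding genes (13.3%). This count follows the length of the list, with 4686 genes in the list of replicate 1, 5976 in that of replicate 2, 5212 in the pooled list and 800 with −log10 q of 5 or more. Zinc finger genes, a large class of transcription factors that includes many repressors of transposable elements, belonged to the 4 of 23 lists that were marked more often than shifted peaks would give. Of 428 such genes, 145 (33.9%) had a replicated peak, against 12.8% of the other genes and 11.4% for shifted peaks (adjusted p = 0.000767, circular-shift permutation test, Benjamini-Hochberg over 23 lists). The shares were 41.1% in the list of replicate 1 and 47.9% in that of replicate 2, where shifted peaks gave 20.7% and 27.2%. Zfp873 (ENSMUSG00000061371, chromosome 10, 82048123 to 82064745) had 15 replicated peaks covering 12.04 kb, 72.4% of its body. Zfp110 on chromosome 7, at 12834761 to 12850577, had 11.6 kb covered (73.2%). Zfp68 on chromosome 5 had 10.3 kb (63.8%) and Zfp606 on chromosome 7 had 9.27 kb (51.7%). Zfp146, on chromosome 7, was covered over 76.1% of its 8.48 kb. Chromosome 7 held 107 of the zinc finger genes, 35 of them with a peak, and chromosome 13 held 42, of which 18 had one.

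Within zinc finger genes the mark sat at the 3′ end. A replicated peak overlapped the last exon of the longest transcript in 109 of the 428 genes (25.5%) and lay within 1 kb of the transcription start site in 8 (1.87%). Of the genes marked at one of these places alone, 105 had the peak on the last exon and 4 at the start (p = 1.78e-26, exact McNemar test, two-sided). Zinc finger genes often lie in clusters and are not independent, so this p is too small. The test also takes no account of the lengths of the last exon and of the window at the start site. With 2.5 kb either side of the start site, 97 had the peak on the last exon alone and 10 at the start alone. At the start site alone the list as a whole did not stand apart from other genes (adjusted p = 0.961, permutation test). Along the gene, the share with a peak rose to 16.1% in a bin near the gene end, against 1.68% over all protein-coding genes.

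**Figure D1:**
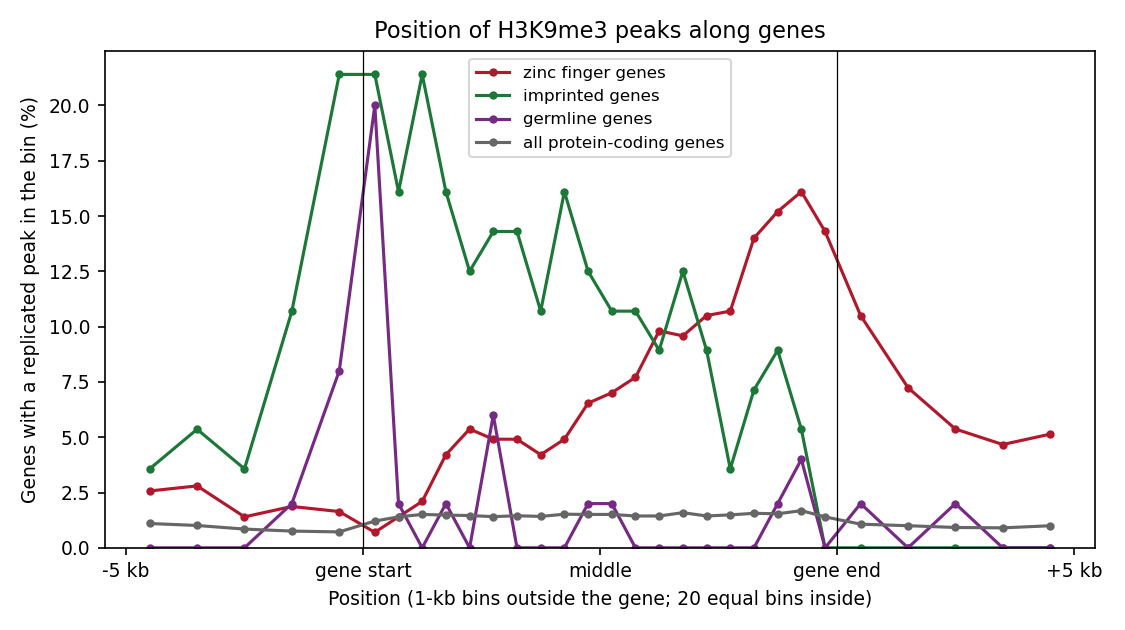
Share of genes (y axis, percent) with a replicated H3K9me3 peak in each position bin (x axis: 1-kb bins over the 5 kb outside the gene and 20 equal bins inside it), for zinc finger, imprinted, germline and all protein-coding genes. Zinc finger genes reach 16.1% near the gene end, and germline genes reach 20.0% in the first bin of the gene.

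Imprinted genes, which are expressed from 1 parental allele, were marked in 33 of 56 cases (58.9%), against 13.1% of other protein-coding genes and 19.02% for shifted peaks (adjusted p = 0.000767, permutation test). Both replicates gave similar shares, 71.4% in replicate 1 and 69.6% in replicate 2, where shifted peaks gave 32.2% and 39.8%. Gnas (ENSMUSG00000027523, chromosome 2, 174284320 to 174346744), which encodes a G protein subunit, had 5 replicated peaks covering 9.39 kb. Grb10, an adaptor of insulin and growth factor receptors on chromosome 11, had 6.50 kb covered. Mest on chromosome 6 had 3.84 kb and Plagl1 on chromosome 10 had 3.51 kb. Klf14, at 30956023 to 30959078 on chromosome 6, was covered over 85.6% of its length by 1 peak with a signal value of 10.5. Cdkn1c, a cyclin-dependent kinase inhibitor on chromosome 7, was covered over 67.6%. A peak lay within 1 kb of the start site in 14 of the 56 genes (against 0.984% of other genes; adjusted p = 0.00115, permutation test). Of the 9 imprinted genes annotated as non-coding, which were not tested, 5 had a replicated peak. They were Airn (5.40 kb covered), Nespas (4.35 kb), Meg3 (2.04 kb), Kcnq1ot1 (1.88 kb) and Peg13 (1.17 kb), while H19, Rian, Mirg and Zim3 had none.

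The clustered protocadherins, cell adhesion proteins of neurons encoded in 3 adjoining arrays on chromosome 18, were marked in 46 of 56 genes (82.1%, against 24.5% for shifted peaks; adjusted p = 0.000767, permutation test). Replicate 1 gave 82.1% and replicate 2 gave 98.2%, with 39.7% and 49.97% for shifted peaks. Pcdhga1 had 78 replicated peaks covering 71.1 kb of its body, Pcdhga2 had 69.1 kb, Pcdhga3 had 66.1 kb and Pcdhgb1 had 61.8 kb. Gene bodies within the Pcdha and Pcdhg arrays overlap and share their last exons, so 1 peak can count for many genes there. In a later search over families, all 11 Pcdha and all 12 Pcdhga genes had a peak (51.8% and 37.7% for shifted peaks). Their adjusted p was 0.927 and 0.781, and that of the Pcdhb genes, with 13 of 22 against 2.30%, was 0.133 (permutation tests). Counting the first exon of each gene alone, an alternative chosen after the data were seen, 39 of the 56 (69.6%) had a peak, against 0.448% of other genes (adjusted p = 0.000767, permutation test). The list was no longer past the threshold with replicated peaks of −log10 q 5 or more (32.1% against 5.91% for shifted peaks; adjusted p = 0.171, permutation test), and its adjusted p otherwise ran up to 0.0172 over the alternatives. The gene models Gm42416, Gm37013 and Gm37388, which span the arrays, had the most covered sequence of all protein-coding genes, at 96.9, 95.4 and 95.1 kb. Pcdhga4 (59.0 kb), Pcdhgb2 (55.7 kb) and Pcdhga5 (52.8 kb) completed the 10 genes with the most sequence covered.

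Germline genes, which are needed in germ cells and kept silent in most other tissues, were marked in 15 of 50 cases (30.0%, against 13.8% for shifted peaks; adjusted p = 0.00632, permutation test). Within 1 kb of the start site, 9 of the 50 (18.0%) had a peak, against 1.01% of other genes (adjusted p = 0.00115, permutation test). The 9 were Dazl, Ddx4, Mei1, Slc25a31, Sohlh2, Stag3, Sycp1, Taf7l and Tdrd1, and of these Mei1 had no peak over its body in the list of replicate 1. Dazl, an RNA-binding protein of germ cells (ENSMUSG00000010592, chromosome 17, 50279395 to 50293636), had the highest signal value of the list's genes, 6.50. Tdrd9 on chromosome 12 had 1.26 kb covered in 3 peaks, Tdrd1 on chromosome 19 had 0.969 kb, Taf7l on chromosome X had 0.795 kb and Ddx4 on chromosome 13 had 0.664 kb. The call over gene bodies rested on replicate 2. Without replicate 2, in the list of replicate 1, 15 of 50 genes had a peak against 25.7% for shifted peaks (adjusted p = 0.946, permutation test), and without replicate 1 there were 25 (adjusted p = 0.0236, permutation test). It was also lost with at least 500 bp of the body covered (6 of 50 against 5.21% for shifted peaks; adjusted p = 0.14) and with pooled peaks found in both replicates (9 of 50 against 9.86%; adjusted p = 0.23, both permutation tests). The 9 start-site genes are named after their values were seen.

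**Figure D2:**
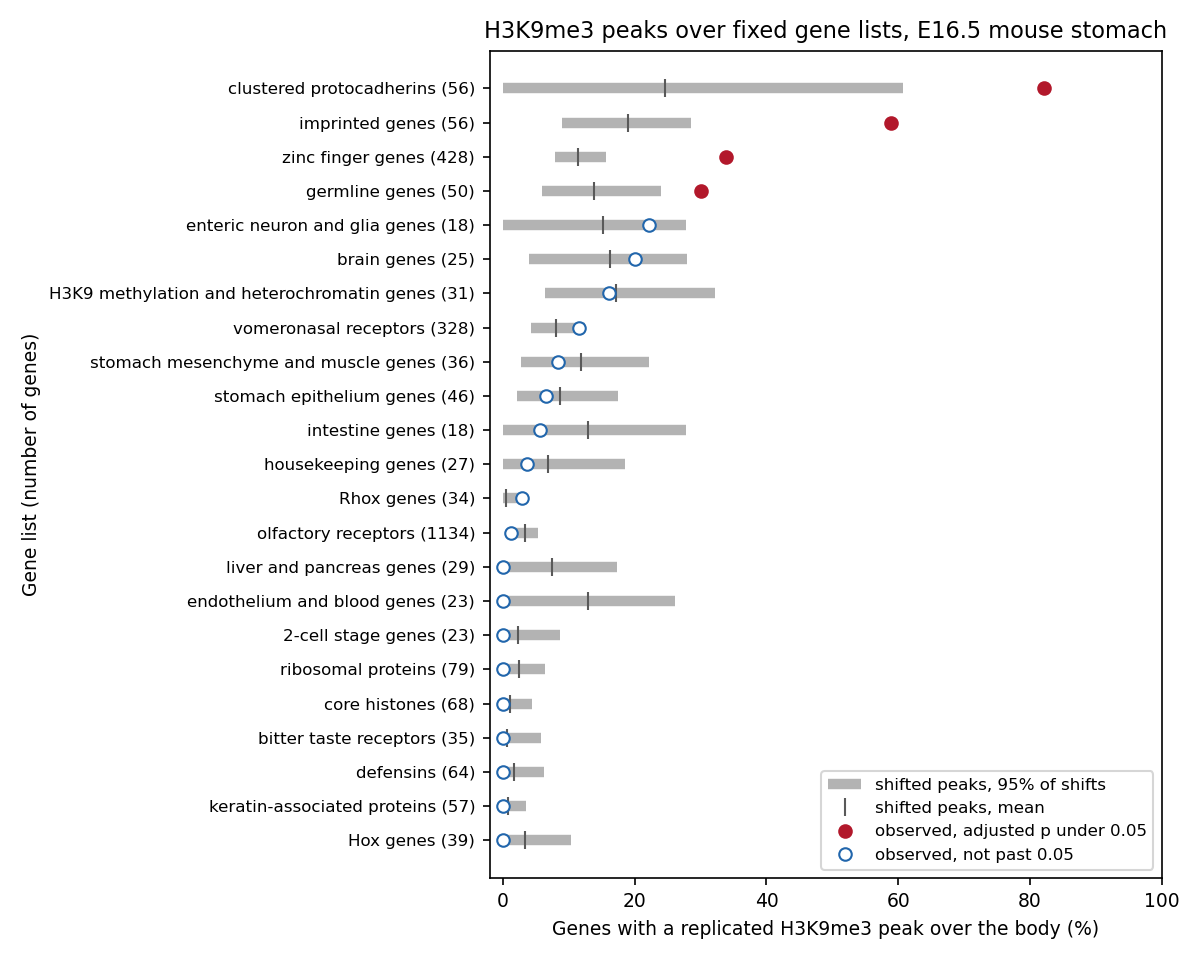
Share of genes with a replicated H3K9me3 peak over the body (x axis, percent) for the 23 gene lists (y axis, number of genes in brackets), with grey bars for 95% of 10000 shifts and a tick for their mean. Filled points, past an adjusted p of 0.05, are the clustered protocadherins (82.1%), imprinted genes (58.9%), zinc finger genes (33.9%) and germline genes (30.0%).

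The other multigene families did not pass the test. Of 1134 olfactory receptor genes, 14 (1.23%) had a replicated peak, against 3.36% for shifted peaks (adjusted p = 0.0603, permutation test). Olfr846 (0.647 kb), Olfr139 (0.432 kb), Olfr943 (0.323 kb) and Olfr137 (0.311 kb) had the most sequence covered. The peaks of Olfr139 and Olfr137 had −log10 q of 1.00 and 0.66, so their q was above 0.05. The list passed the threshold, as lower, with at least 500 bp covered (adjusted p = 0.00997) and with 3 other choices of peaks or null lists besides Fisher's exact test, and stayed short of it in the list of either replicate alone (adjusted p = 0.628 and 0.946, permutation tests). Vomeronasal receptors had a peak in 38 of 328 genes (11.6%, against 8.02% for shifted peaks; adjusted p = 0.276, permutation test). Against random lists matched on gene length that list was higher (adjusted p = 0.0046, permutation test), and its adjusted p ran from 0.0888 to 0.961 over the other alternatives. Vmn1r42 and Vmn1r43 were covered over 1.78 kb by the same 5 peaks, Vmn2r60 over 1.38 kb and Vmn2r53 over 1.22 kb. None of the 39 Hox genes, 57 keratin-associated protein genes, 64 defensin genes, 35 bitter taste receptor genes, 68 core histone genes, 79 ribosomal protein genes or 23 genes of the 2-cell stage had a replicated peak. Short genes gave few peaks after shifting as well, and adjusted p ran from 0.276 to 0.506 in the permutation test. Fisher's exact test, which treats neighbouring genes as independent, called these lists lower apart from the 2-cell stage genes. Of 34 Rhox genes, Rhox13 alone had one (0.382 kb; adjusted p = 0.276, permutation test), and the list of replicate 1 had none there.

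No list of genes of the stomach or of neighbouring or unrelated tissues passed the test. These lists are small, and shifted peaks gave wide ranges, such as 0 to 27.8% of the enteric neuron and glia genes (95% of shifts). A missing call therefore does not show that such genes are marked as often as shifted peaks would give. Of 46 stomach epithelium genes, 3 had a peak (6.52%; adjusted p = 0.543, permutation test), namely the gastric mucin Muc5ac (1.10 kb covered), Onecut2 (0.383 kb) and Grhl2 (0.290 kb). Of 36 genes of stomach mesenchyme and muscle, 3 had one (adjusted p = 0.54, permutation test), namely Pdgfrb (0.371 kb), Ano1 (0.293 kb) and Lmod1 (0.264 kb). The Pdgfrb peak had a −log10 q of 0.56, so its q was above 0.05. Of 18 genes of enteric neurons and glia, 4 had one (adjusted p = 0.506, permutation test): Gfra1 (1.14 kb), Nos1 (0.516 kb), Chat and Snap25 (0.198 kb each). None of 23 endothelium and blood genes (adjusted p = 0.153) and none of 29 liver and pancreas genes (adjusted p = 0.24, both permutation tests) had one. Shifted peaks gave 12.9% and 7.47%. The list of replicate 1 marked 5 and 2 of these genes, and that of replicate 2 marked 4 and 4. Among 18 intestine genes, Lgr5, a stem cell receptor, had 0.268 kb covered (adjusted p = 0.45, permutation test). Of 25 brain genes, 5 were marked (adjusted p = 0.701, permutation test), with Slc17a7, a glutamate transporter, at 2.06 kb, Grin2b at 1.12 kb, Rbfox3 at 0.733 kb, Syt1 at 0.612 kb and Pax6 at 0.233 kb. Among 27 housekeeping genes, Tbp had 0.395 kb covered (adjusted p = 0.543, permutation test), by 1 peak with a −log10 q of 0.56. Of 31 genes of H3K9 methylation and heterochromatin, 5 had a peak (adjusted p = 0.853, permutation test). These were Atf7ip (2.73 kb), a partner of the H3K9 methyltransferase Setdb1, Hells (0.761 kb), Smchd1 (0.622 kb), Pphln1 (0.305 kb) and Morc2a (0.221 kb), of which the last pair had no peak in the list of replicate 1. Within 1 kb of a start site, the genes of these 9 lists had a replicated peak in 1 case, the liver cytochrome P450 gene Cyp3a11 (1 of 29; adjusted p = 0.283, permutation test), whose peak lay outside the gene body and which is named after its value was seen.

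The genes covered over the largest share of their length, among those of 2 kb or more, were Gm21738 (94.4%), Klf14 (85.6%), Ugt1a1 (84.5%), Asmt (82.5%), Zfp146 (76.1%), Zfp110 (73.2%), Il3ra (72.9%), Zfp873 (72.4%), Cdkn1c (67.6%) and Zfp68 (63.8%). The highest signal value was 2.00 in Gm21738 and 2.995 in Ugt1a1, both below the lower quartile of the replicated list (3.07). Ugt1a1, a bilirubin-conjugating enzyme on chromosome 1 at 88211959 to 88218997, had 5.95 kb covered, and Asmt, the last enzyme of melatonin synthesis, lies at 170672644 to 170678054 on chromosome X. The signal value of a peak is the authors' own figure and serves here to rank peaks within a list. The highest, 12.22, belonged to a peak of 5467 bp on an unlocalised scaffold of chromosome 4, which was also the widest. On the chromosomes the highest was 10.5, for the peak at 30956213 to 30958827 over the exon of Klf14. Values of 9.19 followed for a peak over an exon of Pcdhgb6 on chromosome 18 and one over an exon of Pkp4 (chromosome 2, 59318088 to 59319212). A peak over an exon of Zfp865 (chromosome 7, 5029334 to 5032572) had 9.16, one over an exon of Shroom3 on chromosome 5 had 8.22 and one over an exon of Plec (chromosome 15, 76172290 to 76177184) had 8.11. Peaks over exons of 2610008E11Rik, Pcdhgb7 and Zfp606 had 7.75 each, a value that 7 replicated peaks shared. The next widest peaks after the scaffold lay over Zfp110 (5425 bp), over Plec (4895 bp), 2.42 kb from Tmem267 on chromosome 13 (4242 bp) and over Sfi1 on chromosome 11 (4117 bp). The wide peak over Sfi1 had a signal value of only 2.16.

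Peaks held less repeat sequence than their placement by chance would give. Bases marked as repeat in the reference made up 26.4% of the sequence under replicated peaks, against 33.6% for shifted peaks (95% of shifts from 32.6% to 34.5%; p = 0.000999, permutation test). The list of replicate 1 gave 25.5% and that of replicate 2 gave 26.9%. How reads that map to several places were treated is not given in the sources used here, and repeat classes were not analysed here.

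Coverage by replicated peaks differed between chromosomes, from 1371 bp per Mb on chromosome 14 to 3613 bp per Mb on chromosome 7 among the autosomes. Chromosome 17 was next highest at 3553 bp per Mb, followed by chromosome 18 at 2978 bp per Mb. Chromosome X had 468.9 bp per Mb, 0.206 of the autosomal value, and chromosome Y had 43.2 bp per Mb in 5 peaks. The replicates differed on X far more than elsewhere. Replicate 2 had 1961 peaks on X and replicate 1 had 276, a ratio of 7.11, while the ratio on the 19 autosomes ran from 1.34 to 1.60. Coverage of X was 0.144 of the autosomal value in replicate 1 and 0.628 in replicate 2, so the X value depends on which replicate is used. Among peaks with −log10 q of 5 or more, a subset chosen after the data were seen, coverage of X was 0.476 of the autosomal value in replicate 1 and 0.4 in replicate 2. X held 14 of these peaks in replicate 1 and 21 in replicate 2.

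**Figure D3:**
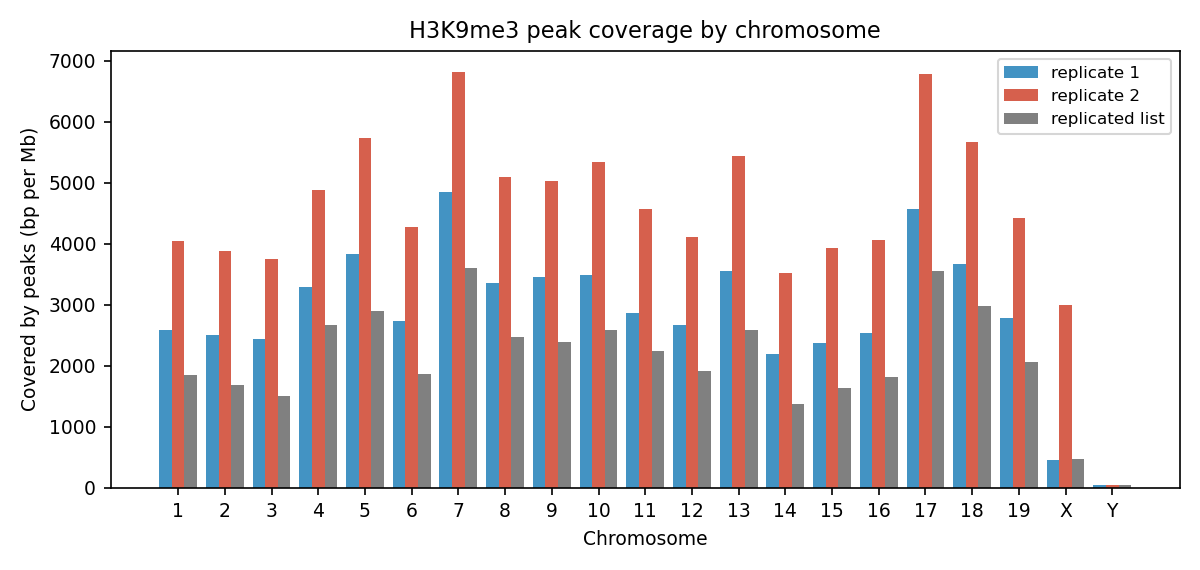
Sequence covered by H3K9me3 peaks (y axis, bp per Mb of sequence) on each chromosome (x axis) in the lists of replicate 1, replicate 2 and the replicated list. On X the bar of replicate 2 reaches 2990 bp per Mb and that of replicate 1 reaches 448.8 bp per Mb.

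The replicates shared a minority of their peaks, at a rate well above chance. On the chromosomes, 9889 of 29239 peaks of replicate 1 (33.8%) overlapped a peak of replicate 2 by 1 bp or more, and 22.3% of the 43850 peaks of replicate 2 overlapped one of replicate 1. Shifted peaks overlapped in 0.935% of cases (p = 0.000999, permutation test). The Jaccard index of the covered sequence was 0.131. Against the whole list of the other replicate, overlap was 87.0% for the 500 most significant peaks of replicate 1 and 85.2% for those of replicate 2, and 23.6% and 14.7% for the least significant. With both lists limited it was lower, at 26.3% and 25.7% for the 5000 most significant peaks of each and 38.6% and 23.2% for peaks with −log10 q of 5 or more. Over shared peaks the signal values of the replicates had a Spearman rho of 0.203 (95% chromosome bootstrap interval 0.17 to 0.233), across peaks, which are not independent replicates. Over the 193 peaks with −log10 q of 5 or more in both, rho was 0.629 (0.463 to 0.762).

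**Figure D4:**
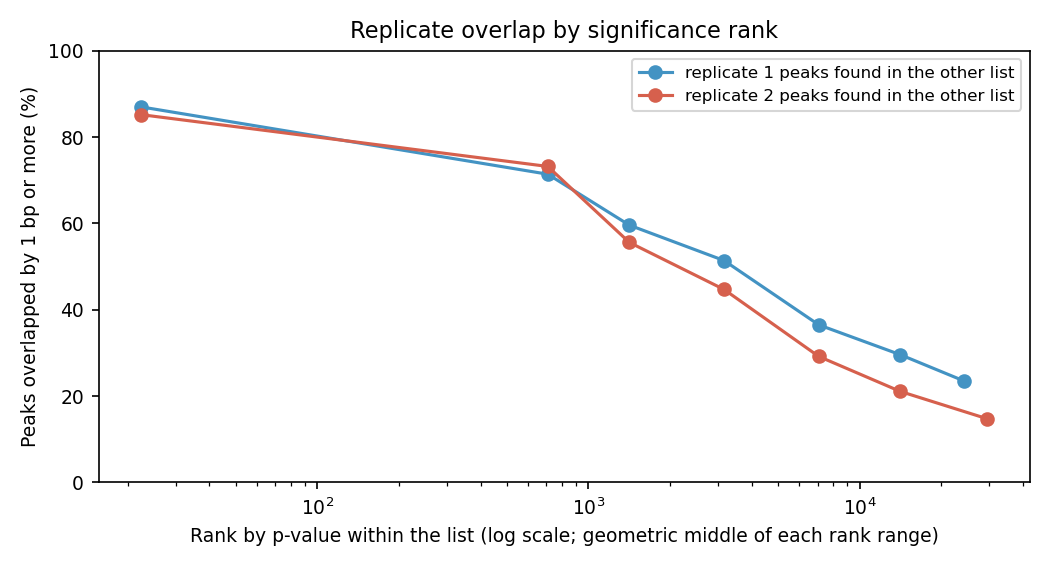
Share of peaks (y axis, percent) of each replicate that overlap a peak of the whole list of the other, by rank of p-value within the list (x axis, log scale). The share falls from 87.0% to 23.6% in replicate 1 and from 85.2% to 14.7% in replicate 2.

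The replicated list kept 37.2% of the pooled peaks. Kept peaks were wider, with a median of 337 bp against 211 bp for the others, and had a median signal value of 3.43 (quartiles 3.07 and 3.93) against 2.88 (2.56 and 3.07). Their median −log10 q was 3.28, against 1.39. These differences describe the selection and were not tested, since the list was chosen on the same libraries. All 9163 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were in the replicated list, along with 4662 that did not.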

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

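Outside the 21 chromosomes, 199 replicated peaks (1.44%) lay on 17 unplaced or unlocalised scaffolds, which the tests of genes, features, repeats and replicate overlap left out. Scaffold Un_JH584304 held 46 and Un_GL456393 held 33. Their median −log10 q was 7.15 against 3.28 on the chromosomes, while the median signal value was 3.34 against 3.43, and 29 of the 100 most significant replicated peaks were on scaffolds.

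The tests of peak numbers on X, of overlap by significance and of signal values below were chosen after the results were seen, and the planned comparison of lists of equal length was put to use as a test of an explanation after its value was seen; the tests of signal ratios on X, of windows on X and of further copies were fixed before their results.

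Replicate 2 had 7.11 times as many peaks on X as replicate 1. A list that is longer on every chromosome is argued against, since the autosomes ran from 1.34 to 1.60. Of the 168 windows of 1 Mb on X, 91.1% held a peak that replicate 1 lacked. That share cannot decide on a few dense regions, since most peaks of replicate 2 are unshared and could fill most windows without an excess. The number per window, a value not fixed beforehand, argues against a few dense regions. Of 1859 such peaks, the median window held 10 and the fullest held 54. An offset of the whole X between immunoprecipitate and control, in replicate 2 or in replicate 1, stays open. Over 107 peaks shared on X the median ratio of signal values was 1.04 (bootstrap 95% interval 0.975 to 1.12), and the autosomes reached from 0.967 to 1.04. Coverage of X was 0.144 of the autosomal value in replicate 1, 0.225 in the pooled list and 0.628 in replicate 2. The lists of replicate 1 and of both replicates pooled derive from 2 further files each, and that of replicate 2 from 1. Whether these files bear on X was not tested. The design holds 1 group, so no biological explanation was tested, and the sex composition of each pool or the inactive X could also differ between the pools.

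The replicates shared 33.8% of replicate 1's peaks. The share of 87.0% among the 500 most significant peaks of replicate 1, against the whole list of replicate 2, is consistent with many unshared peaks lying near the calling threshold, while limiting both lists to −log10 q of 5 or more gave 38.6%. Different list lengths stay open, since taking the same number of top peaks from each (27.5%) can only lower the share of the shorter list. No biological explanation was tested, since both replicates belong to 1 group.

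By median, the most significant peaks had lower signal values than peaks further down the list, although the 1 with the highest value (12.22) was among them. The 20 most significant replicated peaks had a median signal value of 3.35, against 5.91 for the 100 that followed the first 100. A high level of reads at these places in immunoprecipitate and control alike stays open, since the lists give no read level of the control. Of the 15 most significant on chromosomes, 3 (20.0%) had a further copy in the reference over 80% or more of the peak, against 14 of the 100 that followed the first 100 (p = 0.464, Fisher's exact test), so further copies in the reference stay open. Fisher's exact test treats these peaks as independent, although several lie close together, between 3184222 and 3200091 on chromosome 11. The same peaks, and several on scaffold Un_JH584304, are among the 20 behind the median of 3.35. Copies that the reference lacks could not be examined, and no biological explanation was tested.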

How the results depend on the processing

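The first-exon setting, the setting of pooled peaks found in both replicates, and the X values at −log10 q of 5 or more were chosen after the data were seen; the others were planned. Over 10 alternatives to each of the 23 gene lists, 180 of 230 values kept their direction and their side of an adjusted p of 0.05. Direction here is that of the tested difference, a list's share minus that of the other genes, relative to its mean over shifts. A list's own share lay on the other side of its shifted mean in 14 of the 230, none past the threshold. Of the other results, 37 of 53 kept their direction and their call, or stayed within their spread where no test was made. The covered kb of the named genes are not part of this count. The imprinted genes were higher in all 10, with adjusted p up to 0.00115. No paired analysis was possible because the series has 1 group. The list of replicate 1 or replicate 2 alone stands for leaving the other out. Unless stated, p-values are adjusted p-values of permutation tests, and the cause of a change was not tested. Read depth is unknown, so what depth limits could not be measured.

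Calls lost, with the share beside that of shifted peaks, were the zinc finger genes at start sites (0.961, 1.87% against 1.42%) and in the first exon (0.186, 1.17% against 0.436%), the protocadherins with −log10 q of 5 or more (0.171, 32.1% against 5.91%), and the germline genes with 500 bp covered (0.14, 6 of 50 against 5.21%), with pooled peaks found in both replicates (0.23, 9 of 50 against 9.86%) and without a replicate (0.0236 to 0.946, lost without replicate 2). Olfactory receptors became called as lower with −log10 q of 5 or more (0.0107), 500 bp covered (0.00997), pooled peaks found in both replicates (0.0195), Fisher's exact test (2.14e-50) and length-matched lists (0.000575). Length-matched lists, a test that shifts no peaks and treats neighbouring genes as independent, called vomeronasal receptors as higher (0.0046). Fisher's exact test, which treats neighbouring genes as independent, called as lower Hox genes (0.017), keratin-associated proteins (0.00164), defensins (0.000853), bitter taste receptors (0.0233), core histones (0.000389) and ribosomal proteins (0.000145).

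The tested difference turned, short of the threshold, in these cases. In 7 of the 32 the list's own share stayed on its side of shifted peaks, namely Hox genes, defensins and core histones with the pooled list, keratin-associated proteins, core histones and 2-cell stage genes without replicate 1, and endothelium and blood genes without replicate 2. With the pooled list the tested difference turned for Hox genes (0.951), defensins (0.98), bitter taste receptors (0.379), core histones (0.98) and brain genes (0.925). With −log10 q of 5 or more it did for vomeronasal receptors (0.143), Rhox genes (0.107) and heterochromatin genes (0.69). With 500 bp covered it did for Rhox (0.14) and heterochromatin genes (0.72). At start sites it did for defensins (0.961), enteric (0.961), liver and pancreas (0.283) and brain genes (0.961). In the first exon it did for vomeronasal receptors (0.723), enteric (0.186) and brain genes (0.211). It also did with pooled peaks found in both replicates for Rhox genes (0.23), with Fisher's exact test for vomeronasal receptors (0.474), Rhox (0.12) and heterochromatin genes (0.62), and with length-matched lists for Rhox genes (1.0). Leaving out a replicate turned it for Hox genes (0.628 to 0.946), keratin-associated proteins (0.667 to 0.946), bitter taste receptors (0.0888 to 0.148), core histones (0.832 to 0.946), 2-cell stage genes (0.946 to 1.0), stomach epithelium (0.832 to 0.946), endothelium and blood (0.471 to 0.946), intestine (0.533 to 0.946) and brain genes (0.832 to 0.946).

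The promoter share was called lower in the pooled list (1.32%), and in 1 of the replicates alone (1.41% to 1.49%, called in replicate 1), and lay above that of shifted peaks with −log10 q of 5 or more (2.69%). The intron share lost its call with −log10 q of 5 or more (36.3%) and with pooled peaks found in both replicates (35.2%). The share between genes was called higher in the pooled list (61.5%) and in each replicate (60.9% to 62.3%), and turned lower with pooled peaks found in both replicates (56.8%) and with −log10 q of 5 or more (49.98%, called). Rho rose to 0.629 with −log10 q of 5 or more. X coverage relative to autosomes ran from 0.144 to 0.628 between the replicates. Protein-coding genes with a peak numbered 2905, against 5212 in the pooled list, 4686 to 5976 in the replicates and 800 with −log10 q of 5 or more. Since the lists differ in length, these counts follow the number of peaks.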

Other observations

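The tests of gene biotypes and of families by symbol were chosen after the data were seen, as were the counts in dense windows, which were not tested. The 2 tests of repeat sequence near peaks were fixed before their results.

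Some other kinds of genes were marked more often than shifted peaks would give, and 4 are named here. The annotation's 19 biotypes of 100 or more genes were tested together. Among 5854 long intergenic non-coding RNA genes, 490 (8.37%) had a replicated peak, against 7.01% for shifted peaks (adjusted p = 0.00633, permutation test). Processed pseudogenes had one in 95 of 9940 cases (0.956% against 0.581%; adjusted p = 0.00633), and genes annotated as miscellaneous RNA in 12 of 562 (2.14% against 0.335%; adjusted p = 0.00633, both permutation tests). Immunoglobulin V pseudogenes had one in 5 of 158 cases (3.16% against 0.374%; adjusted p = 0.0142, permutation test). Protein-coding genes as a whole did not differ (13.2% against 13.1%; adjusted p = 0.849, permutation test). In an open search over 356 families of 8 or more protein-coding genes that share a symbol stem, only the Zfp genes passed an adjusted p of 0.05 (140 of 394; adjusted p = 0.0356, permutation test), most of which the zinc finger list of the report already holds. The next were Dnajb (5 of 13), Kbtbd (4 of 9) and Pcdhb genes (13 of 22), each with adjusted p = 0.133 in the permutation test.

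The mark was concentrated along the genome. The 100 densest of 2737 windows of 1 Mb held 26.0% of the sequence under replicated peaks, and 36 of them held a zinc finger gene, against 7.42% of all windows, while 514 windows had no replicated peak. The densest, from 37000001 to 38000000 on chromosome 18, held the protocadherin arrays, with 94.3 kb covered. Next was 82000001 to 83000000 on chromosome 10, with Zfp873 and Zfp938 (49.7 kb). The window from 88000001 to 89000000 on chromosome 1 held the Ugt1a genes, which encode glucuronosyltransferases (45.1 kb). A window of chromosome 12, from 114000001 to 115000000, had 53 peaks and 18.3 kb covered without any gene annotated as protein-coding. Genes of other biotypes, immunoglobulin V genes among them, were not counted in the windows.

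The lower repeat content of peaks may arise where reads from inside repeats cannot be placed, so that peaks are called beside them. Sequence within 1 kb of replicated peaks was 34.2% repeat, against 33.6% for shifted peaks (p = 0.043, permutation test), a small excess in line with this hypothesis. That value sits at the edge of the 95% range of shifts (32.92% to 34.24%), and its p was not adjusted over the tests of explanations made. Of replicated peaks, 2.23% lay inside or within 1 kb of an unbroken repeat block of 5 kb or more, against 3.84% for shifted peaks (p = 0.000999, permutation test). Peaks were thus fewer in and around such blocks. Shifted peaks can fall inside a block where reads may not be placed, so this count cannot decide whether peaks gather at block edges.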
